A study of Homo sapiens with 12 samples.

How the data were processed

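RNA was measured in 3 human multiple myeloma cell lines (KMS-11, KMS-12 and RPMI8226) after 72 h with 1 µM JQ1 or with DMSO, with 2 libraries for each of the 6 groups and 12 in all. Per the labels' protocols, total RNA was extracted and stranded libraries were made after removal of ribosomal RNA. The deposited table holds raw read counts, whole numbers for each of 60666 Ensembl gene IDs and each library. The submitters' processing notes name the builds hg38 and GRCh38.p13 and the tools DESeq2 and MACS2, without a role. The aligner, the counting program, the annotation release and whether counting used the strand are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as histone, immunoglobulin and small nucleolar RNA genes, are therefore uncertain. Of the IDs in the table, 19667 had no read in any library.

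Depth ran from 15424512 to 27366499 counts per library. A floor of 3 counts, the upper limit that 0 reads allow, corresponds to between 0.107 and 0.178 CPM in 1 library. CPM were computed from the deposited counts with TMM-scaled library sizes. Bounds and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Fold changes against a group with no read in any library are given as a bound, with the floor of 3 counts set over the group. In all, 4541 of the genes tested had no read in at least 1 group.

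Groups were taken from the line and treatment labels. In R 4.3.3, edgeR 4.0.16 was used on the deposited counts with filterByExpr over the 6 groups (minimum count 10, minimum total 15). This kept 23493 genes (38.7%) and 99.90% to 99.96% of the counts in each library. TMM scaling, estimateDisp, glmQLFit with robust estimation and quasi-likelihood F tests followed. A single fit with a mean for each of the 6 groups served every comparison, so that the lines share an estimate of the spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were the mean of the 3 JQ1 minus DMSO differences, each line alone, the 3 pairwise differences of responses, and an F test of any difference between the lines. Standard errors are the log2 fold change divided by the square root of F and are not given where a group had no reads. A gene without reads in the 4 libraries of a line (2651 of those tested) cannot be called in the average of the lines. Read counts, CPM and fold changes refer to relative amounts, since no spike-in was used.

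Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way; the Benjamini-Hochberg adjustment ran over the 26 of 27 lists with at least 5 measured members. Symbols came from a gene name table that paired 60437 of the IDs (99.62%), and gene classes and GRCh38 positions from GENCODE 29, which holds 58420 of them (96.3%). The share of long non-coding RNA genes called was set beside that in 10000 random sets of protein-coding genes matched on mean expression, as a description. SMILO is listed as another name of LINC00582 in the RefSeq gene table.

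Before the data were examined, the lists, the tests, the alternatives and the rule for named genes were fixed. The rule leaves out XIST, Y-linked genes and genes known only by an ID or clone name. It takes the 10 largest rises and 10 largest falls in the average of the lines (adjusted p under 0.05, mean of at least 1 CPM, both JQ1 libraries on the same side of both DMSO libraries in each line), 5 and 5 by the same rule in each line, 5 and 5 among long non-coding RNA genes, and the 10 genes with the smallest p for a difference between lines. FLI1, MYC, IRF4, PRDM1, BRD2, BRD3, HEXIM1, SERPINI1, CDKN1A, BCL2, MCL1 and SMILO were always taken, as were up to 4 members of each list with the smallest adjusted p. Some genes that the rule takes are not reported here. Genes at myeloma translocations served as a check of the line labels.

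The alternatives were RLE scaling, library size alone, TMM after leaving out immunoglobulin, mitochondrial, histone and 7SK/7SL genes, no filter beyond 1 read, a mean of at least 10 CPM, DESeq2 1.42.0 (Wald tests, and a likelihood ratio test for the difference between lines), limma-voom, blocks for the replicate number, a test against 1.5-fold, and leaving out each library in turn. Where a library was left out, the remaining library of its group was assumed to vary like the other groups. The code was tested on simulated counts of the same genes and depths: for the average of the lines it recovered 61.2% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 92.4% of those changed 4-fold, with 5.56% of its calls false; for KMS-11 alone it recovered 28.4%, 56.7% and 90.9%, with 10% false. No difference between lines was simulated, and 2 of 23493 genes were called for one. A list raised 1.5-fold was called, with 0 other lists. The gene simulations changed 67 genes 1.5-fold, 67 genes 2-fold and 66 genes 4-fold, some up and some down. All simulations drew each gene independently. They do not cover a large shift in composition or genes that vary together. Replicates within each group differed by more than sampling noise, so no pair was taken for copies of 1 library; this does not show that they came from separate cultures.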

Results

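RNA from 3 human multiple myeloma cell lines was sequenced after 72 h with 1 µM JQ1 or with its solvent DMSO. JQ1 occupies the acetyl-lysine pockets of the BET proteins, readers of acetylated histones that bring elongation factors to active genes. KMS-11, KMS-12 and RPMI8226 each gave 2 JQ1 and 2 DMSO libraries, 12 in all, with totals between 15424512 and 27366499 counts. The labels do not say whether replicates came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical. Within each group the replicates differed by more than sampling noise, with a chi-square per degree of freedom between 6.11 and 25.01 over 16634 to 19214 genes per group.

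The series concerns the long non-coding RNA SMILO and its control by the transcription factor FLI1, and the question put to these libraries was how JQ1 affects transcripts active in myeloma. SMILO (LINC00582, ENSG00000229228; chromosome 1, 231591292 to 231612090, minus strand, GRCh38) had 47 reads over the DMSO libraries and 0 over the JQ1 libraries, so that its level was at least 12.2-fold lower over the 3 lines. In KMS-11 both DMSO libraries had 12 reads, in KMS-12 they had 4 and 0, and in RPMI8226 they had 6 and 13. The fall was at least 6.33-fold in KMS-11 and at least 5.44-fold in RPMI8226, while a difference in KMS-12 was not detectable at this depth. The edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.000977 for the average of the lines, 0.00703 for KMS-11 and 0.0133 for RPMI8226. The average rests on KMS-12 DMSO replicate 1: without it KMS-12 has no SMILO read and edgeR's Benjamini-Hochberg adjusted p was 1.00, the top of a range from 1.82e-05 over the alternatives. The RPMI8226 call was lost without DMSO replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0800), JQ1 replicate 1 (0.0812) or JQ1 replicate 2 (0.0538), in a range from 0.00195 to 0.0812.

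**Figure D1:**
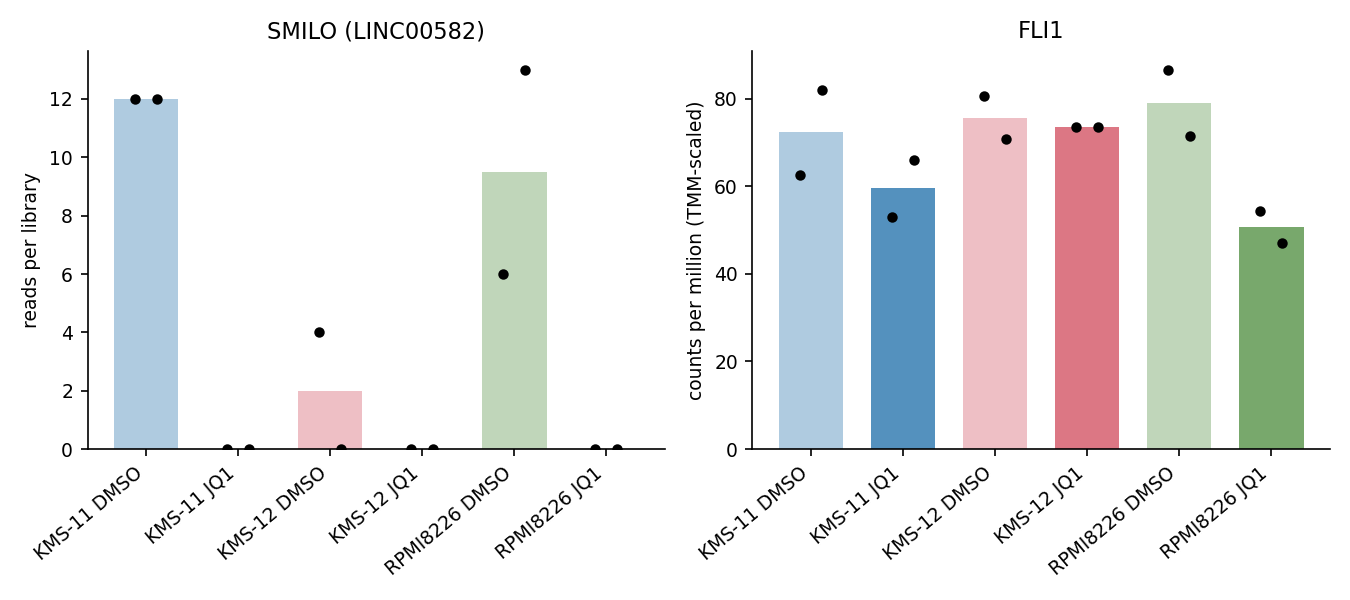
Reads of SMILO (left, reads per library) and level of FLI1 (right, CPM after TMM scaling) in each library; bars are group means and points the 2 libraries of a group. SMILO had 0 reads in every JQ1 library, and FLI1 in RPMI8226 fell from a mean of 79.0 to 50.8 CPM.

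FLI1 (ENSG00000151702; chromosome 11, 128686535 to 128813267, plus strand), the ETS factor named with SMILO, fell by 0.32 on the log2 scale in the average of the lines (SE 0.08, n = 2 libraries per group; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00401). In RPMI8226 it fell from 79.0 ± 10.8 to 50.8 ± 5.24 CPM (SD, n = 2), a log2 change of -0.64 (SE 0.14; edgeR, Benjamini-Hochberg adjusted p = 0.00303). The value was -0.28 in KMS-11 (SE 0.14) and -0.04 in KMS-12 (SE 0.14), neither past the test. Leaving out a KMS-11 DMSO library moved the average both ways, to -0.38 without replicate 1 and to -0.25 without replicate 2. Without DMSO replicate 1, KMS-11 itself stood at -0.47, and KMS-12 without its DMSO replicate 1 stood at 0.06. With library size alone FLI1 passed in both, at -0.54 in KMS-11 and -0.81 in KMS-12 (edgeR, Benjamini-Hochberg adjusted p = 3.64e-05 in KMS-12, in a range up to 1), and stood at -0.67 in the average. The responses of the lines did not differ past the test (edgeR, Benjamini-Hochberg adjusted p = 0.0858). Against a fold of 1.5 the average did not pass (edgeR, Benjamini-Hochberg adjusted p = 1, in a range from 6.83e-07 to 1 over the alternatives).

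Across the 3 lines together, JQ1 raised HEXIM1, an inhibitor of the elongation kinase P-TEFb, by a log2 value of 2.61 (SE 0.07), from 21.9 ± 2.22 to 121 ± 1.21 CPM in KMS-11, 23.0 ± 2.35 to 189 ± 12 in KMS-12 and 20.3 ± 0.591 to 101 ± 18.6 in RPMI8226 (SD, n = 2; edgeR, Benjamini-Hochberg adjusted p = 1.13e-13 for the average). The largest rises by the fixed rule were IQCN at 4.94 (SE 0.14), EFR3B at 4.34 (SE 0.30), SRPK3 at 3.34 (SE 0.30), NQO1 at 3.07 (SE 0.13), a quinone reductase of the oxidative stress response, and MAP1A at 2.87 (SE 0.12). FAM222A, the secreted chaperone CLU, PEG10, EPPK1 and SNORD3B-2 followed at 2.87, 2.73, 2.73, 2.72 and 2.71. HSD17B14, a steroid dehydrogenase, fell by 5.95 (SE 0.27) and had 830 DMSO and 13 JQ1 reads in KMS-11, 711 and 8 in KMS-12, and 111 and 1 in RPMI8226. Without KMS-12 DMSO replicate 1 EFR3B, average of the 3 lines, had a fitted value of 5.01, and HSD17B14, average of the 3 lines, had -6.59 without KMS-12 JQ1 replicate 2 and -6.79 without RPMI8226 JQ1 replicate 2. The long non-coding RNAs LINC01226 and UICLM, RUFY4, TFEC, FSD2, IGHG2, ADGRG1, IFITM1 and TSKU completed the largest falls, each with no JQ1 read in at least 1 line. TFEC, a MiT family transcription factor gene, fell by 7.45 in RPMI8226 (SE 0.23), from 5333 to 26 reads. ADGRG1 had 1503 DMSO and 17 JQ1 reads in KMS-11, and was at least 9.32-fold lower in KMS-12. The 18 of these 20 genes other than RUFY4 and IFITM1 had an edgeR Benjamini-Hochberg adjusted p of 2.17e-06 or less for the average.

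MYC, the oncogenic transcription factor whose fall is the classic JQ1 readout in myeloma, fell by 0.64 (SE 0.11; edgeR, Benjamini-Hochberg adjusted p = 0.000415). It fell from 367 ± 24.8 to 199 ± 9.62 CPM in KMS-12. Its log2 value was -0.47 (SE 0.19) in KMS-11, which did not pass the test, and -0.56 (SE 0.19) in RPMI8226. MYC in RPMI8226 passed at an edgeR Benjamini-Hochberg adjusted p of 0.0410 (4.94e-05 to 0.772 over the alternatives), lost without any single KMS-12 library (-0.56), KMS-11 DMSO replicate 2 (-0.57), or RPMI8226 DMSO replicate 1 (-0.41), JQ1 replicate 1 (-0.63) or JQ1 replicate 2 (-0.49). MYC in KMS-11 stood at -0.80 without its JQ1 replicate 1. The KMS-11 value was smaller in size without JQ1 replicate 2. MYC had 362 and 241 CPM in JQ1 replicates 1 and 2 of KMS-11, against 478 and 359 in DMSO. BCL2, an inhibitor of cell death, fell by 0.56 (SE 0.06), and by 0.72, 0.39 and 0.58 in KMS-11, KMS-12 and RPMI8226. PRDM1, the plasma cell factor BLIMP1, rose by 1.18 (SE 0.08), and BRD2 rose by 0.78 (SE 0.06). BRD3 fell by 0.32 (SE 0.06), an average that rested on KMS-12 at -1.05 (SE 0.10). Its log2 value in RPMI8226 lay 1.20 above that of KMS-12 and so was not a fall. SERPINI1 at 0.29 (SE 0.09) passed the test narrowly (edgeR, Benjamini-Hochberg adjusted p = 0.0142); with library size alone it turned to -0.06. It was lost without KMS-12 DMSO replicate 1 (0.26) or RPMI8226 DMSO replicate 2 (0.24).

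In the average of the lines edgeR called 11509 of 23493 genes at a Benjamini-Hochberg adjusted p under 0.05, 5244 higher and 6265 lower with JQ1. By 2-fold or more, 873 were higher and 3181 lower. Of the calls, 45.6% were higher, against 16.97% with library size alone. That scaling moved the median of all genes by -0.33 in the average, -0.25 in KMS-11, -0.76 in KMS-12 and -0.03 in RPMI8226. In all 3 lines, 1420 genes were higher and 1496 lower, where independent lists would share 112 and 239.

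In the average of the lines, genes of mitosis, DNA replication and ribosomal proteins were mostly lower. For DNA replication and for replication-dependent histones that average joins opposite responses, since in RPMI8226 34 and 20 of these genes rose (38 and 28 adjusted over the list alone) and 0 fell. Of 40 mitosis genes, 37 fell and 0 rose, with a median log2 change of -2.15. Among them were MAD2L1 at -1.73 (SE 0.16), CENPA at -2.50 (SE 0.25), PRC1 at -1.96 (SE 0.23) and the ubiquitin-conjugating enzyme UBE2C at -3.65 (SE 0.38). Of 45 DNA replication and S phase genes, 31 fell and 3 rose (median -0.63), among them the origin factors CDC6 at -1.71 (SE 0.10), CDC45 at -2.93 (SE 0.24), MCM6 at -0.80 (SE 0.07) and ORC1 at -1.83 (SE 0.15). Of 40 replication-dependent histone genes, 16 fell and 2 rose (median -0.84), H2BC13 at -1.92 and H3C2 at -2.98 among the falls and H2BC6 at 0.89 among the rises. Of 69 ribosomal protein genes, 59 fell and 0 rose (median -0.34), with RPS19 at -0.91 (SE 0.06) and RPL13A at -0.75 (SE 0.06). Of 19 snoRNA host genes, 14 fell and 3 rose (median -0.36), SNHG29 at -0.65 and SNHG16 at -0.60 among the falls and SNHG12 at 1.10 among the rises. Of 31 unfolded protein response genes, 18 fell and 2 rose (median -0.29), including the sensor ERN1 at -0.99 (SE 0.07) and EDEM1 at -0.94 (SE 0.07), which sends misfolded proteins to degradation. This average joins unlike responses too: 25 fell and 0 rose in KMS-11, while 14 rose and 4 fell in KMS-12 (4 and 14 with library size alone).

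In the average of the lines, rises outnumbered falls in 4 further lists that camera called. Of 22 BET protein and elongation factor genes, 16 rose and 5 fell, with a median of 0.27 that turned to -0.09 with library size alone; AFF1 at 0.50 and AFF4 at 0.59, scaffolds of the super elongation complex, rose beside HEXIM1 and BRD2. Of 15 polyadenylated and linker histone genes, 10 rose and 2 fell (median 0.51), H1-10 at 1.31 (SE 0.13) and H3-3A at 0.60 (SE 0.06) among the rises and H2BC12 at -1.23 (SE 0.11) among the falls. Of 38 autophagy and lysosome genes, 18 rose and 7 fell, or 20 and 8 adjusted over the list alone, with a median of 0.19 that turned to -0.17 with library size alone. This rise rested on KMS-12, where 24 rose and 3 fell. In KMS-11 14 rose and 12 fell (median -0.02), and in RPMI8226 4 rose and 12 fell (median -0.04). ATP6V0D1, a subunit of the lysosomal proton pump, rose by 1.23 (SE 0.06) and the sialidase NEU1 by 0.93 (SE 0.06), while the cysteine protease CTSS fell by 3.07 (SE 0.09) and WIPI1 by 1.13 (SE 0.07). Of 13 mitochondrially encoded genes, 12 rose and 0 fell (median 0.54), with MT-ATP8 at 0.75 and MT-CYB at 0.65. With library size alone the mitochondrial list had 6 rises and 1 fall (median 0.19) and the polyadenylated histones 5 rises and 3 falls (median 0.16). For the 9 lists other than the autophagy list, the counts adjusted over the list alone were equal to those with TMM scaling over all genes.

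Camera called these 10 of 26 lists at a Benjamini-Hochberg adjusted p under 0.05. The values were 1.40e-09 for mitosis, 7.19e-08 for ribosomal proteins, 0.000152 for mitochondrial genes, 0.00127 for DNA replication, 0.00417 for BET and elongation factors, 0.00925 for replication-dependent histones, 0.0135 for polyadenylated histones, 0.0140 for autophagy, 0.0173 for the unfolded protein response and 0.0423 for snoRNA hosts (camera in limma, Benjamini-Hochberg adjusted p). None held with an estimated correlation, the smallest being adjusted p = 0.576 with an estimated correlation, and 0 lists had an unadjusted p under 0.05 in that camera test, while fry called 23. Over the alternatives camera's Benjamini-Hochberg adjusted p reached 0.0651 for snoRNA hosts without KMS-12 DMSO replicate 1 (from 0.00607), 0.0552 for the unfolded protein response without KMS-11 DMSO replicate 1 (from 0.00213), 0.0619 for polyadenylated histones at a mean of at least 10 CPM (from 0.00162), and with library size alone 0.189 for the BET list (from 0.000402) and 0.360 for autophagy (from 0.00162).

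The other lists were not called in the average, and some were called under an alternative. The MYC list was called in 5 of 20 alternatives, NF-kB targets in 3, plasma cell genes in 2, the interferon list in 1, and the T and NK cell and stromal lists in 1 of 19 each. With library size alone 47 MYC targets fell and 3 rose, with a median of -0.54 (camera, Benjamini-Hochberg adjusted p = 0.000386, in a range up to 0.113). MYC and its nucleolar targets otherwise had 25 falls and 8 rises among 57 (26 and 8 adjusted over the list alone; median -0.19), with the chaperonin HSPD1 at -1.10 and the folate carrier SLC19A1 at -1.40, and with ODC1 at 1.38 and BOP1 at 0.82 among the rises. Plasma cell and myeloma identity genes had 13 falls and 5 rises among 26 (median -0.49), with ITGA4 at -1.84 (SE 0.07), MZB1 at -1.93 (SE 0.10) and CD28 at -1.30 (SE 0.10). MHC and antigen presentation genes had 13 falls and 6 rises among 22 (median -0.49), with HLA-DRA at -1.46, HLA-DQA1 at -2.27, HLA-DMA at -1.24 and the immunoproteasome subunit PSMB8 at -1.79. ETS family genes had 8 falls and 3 rises among 21 (median -0.23, and -0.30 with genes without reads at their bound). Among the falls were ELF4 at -0.81, ERF at -0.80 and GABPA at -0.37. Cell cycle inhibitors and p53 targets had 13 rises and 8 falls among 26, with GADD45B at 1.75 and TP53INP1 at 0.90 against TNFRSF10B at -1.81. They had a median of 0.21 that turned to -0.15 with library size alone. NF-kB targets had 9 rises and 4 falls among 23, NFKBIA at 1.30 against PLEK at -1.92 and TRAF1 at -0.74. They had a median of 0.19 that turned to -0.16 with library size alone.

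Among 14 BCL2 family genes 4 rose and 4 fell (5 and 4 adjusted over the list alone); the death promoter BCL2L11 (BIM) rose by 1.18 (SE 0.07) and BMF by 0.57 (SE 0.06). The list's median of 0.14 turned to -0.21 with library size alone. Interferon response genes had 6 falls and 4 rises among 39 (5 and 4 adjusted over the list alone; median -0.40, and -0.31 at the bounds), STAT2 at 0.68 against ISG20 at -1.18, IFIH1 at -0.52 and IFITM3 with 11 DMSO and 0 JQ1 reads in KMS-12. Cholesterol synthesis genes had 9 falls and 6 rises among 24 (10 and 6 adjusted over the list alone), FDPS at -0.83 and STARD4 at -0.69 against IDI1 at 0.77 and TM7SF2 at 0.68. They had a median of -0.08 and a mean of -0.03 where camera's direction was up. Blood markers of BET inhibitor exposure had 5 rises and 3 falls among 10 while their median was -0.17; ZMYND8 fell by 1.42 (SE 0.06) and ZCCHC24 rose by 0.52 (SE 0.11), which was 0.17 and not past the test with library size alone. Well-studied long non-coding RNAs had 8 rises and 9 falls among 29 (8 and 10 adjusted over the list alone), with a median of 0.04 that was -0.05 at the bounds and -0.31 with library size alone, and a mean of -0.03. Genes at myeloma translocations had 2 rises and 3 falls among 10, with a median of 0.19 that was -0.10 at the bounds and -0.16 with library size alone.

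Lists of other cell types were used to look for other cells in the cultures, although some of their members were well read in these lines. In DMSO, KRT18 had 1967 reads and NCAM1 1726 in RPMI8226, and EPCAM had 1320 in KMS-11. Of 13 B cell markers 5 fell and 1 rose (median -1.47), with CD79A at -2.44 (SE 0.28), BLK at -2.53 (SE 0.41), BANK1 at -2.71 (SE 0.55) and CD79B at -3.01 (SE 0.58), the last not past the test without RPMI8226 DMSO replicate 1 (-2.08). Of 8 T and NK cell markers 4 fell and 1 rose (median -1.13, and -1.39 at the bounds), with CD3E at -4.13 (SE 0.52), CD8A at -1.21 (SE 0.23) and CD247 at -1.01 (SE 0.24); the rise was NCAM1, at 2.16 in KMS-11 (SE 0.25) and 0 to 3 reads in KMS-12, lost in the average without KMS-12 JQ1 replicate 1. Of 7 stromal and epithelial markers 5 fell (median -1.99, and -1.51 at the bounds), among them EPCAM at -1.99 (SE 0.10) and PECAM1 at -3.48 (SE 0.27), with CDH1 (-2.36, SE 0.69) lost without RPMI8226 DMSO replicate 2 (-1.74), and KRT18, with 3 to 0 reads in KMS-12, lost without KMS-12 DMSO replicate 2. Leaving out 1 JQ1 library moved fitted values further from 0: BLK, average of the 3 lines, to -3.35 (KMS-11 replicate 1), BANK1, average of the 3 lines, to -3.55 (KMS-11 replicate 2) and CD79B, average of the 3 lines, to -3.85 (RPMI8226 replicate 2). In the same way CD3E, average of the 3 lines, moved to -5.66 and -5.25 (KMS-12 replicate 1 and KMS-11 replicate 2), and CDH1, average of the 3 lines, to -3.20 and -3.21 (KMS-11 and RPMI8226 replicate 2). Of 6 myeloid markers none passed in the average (median -1.36, and -0.94 at the bounds); ITGAM passed at -0.66 without RPMI8226 JQ1 replicate 2, and LYZ turned from 0.45 to -0.69 without the same library. ITGA2B, the only erythroid and platelet marker measured, had a value of -0.17, which became 0.04 without KMS-12 JQ1 replicate 2.

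**Figure D2:**
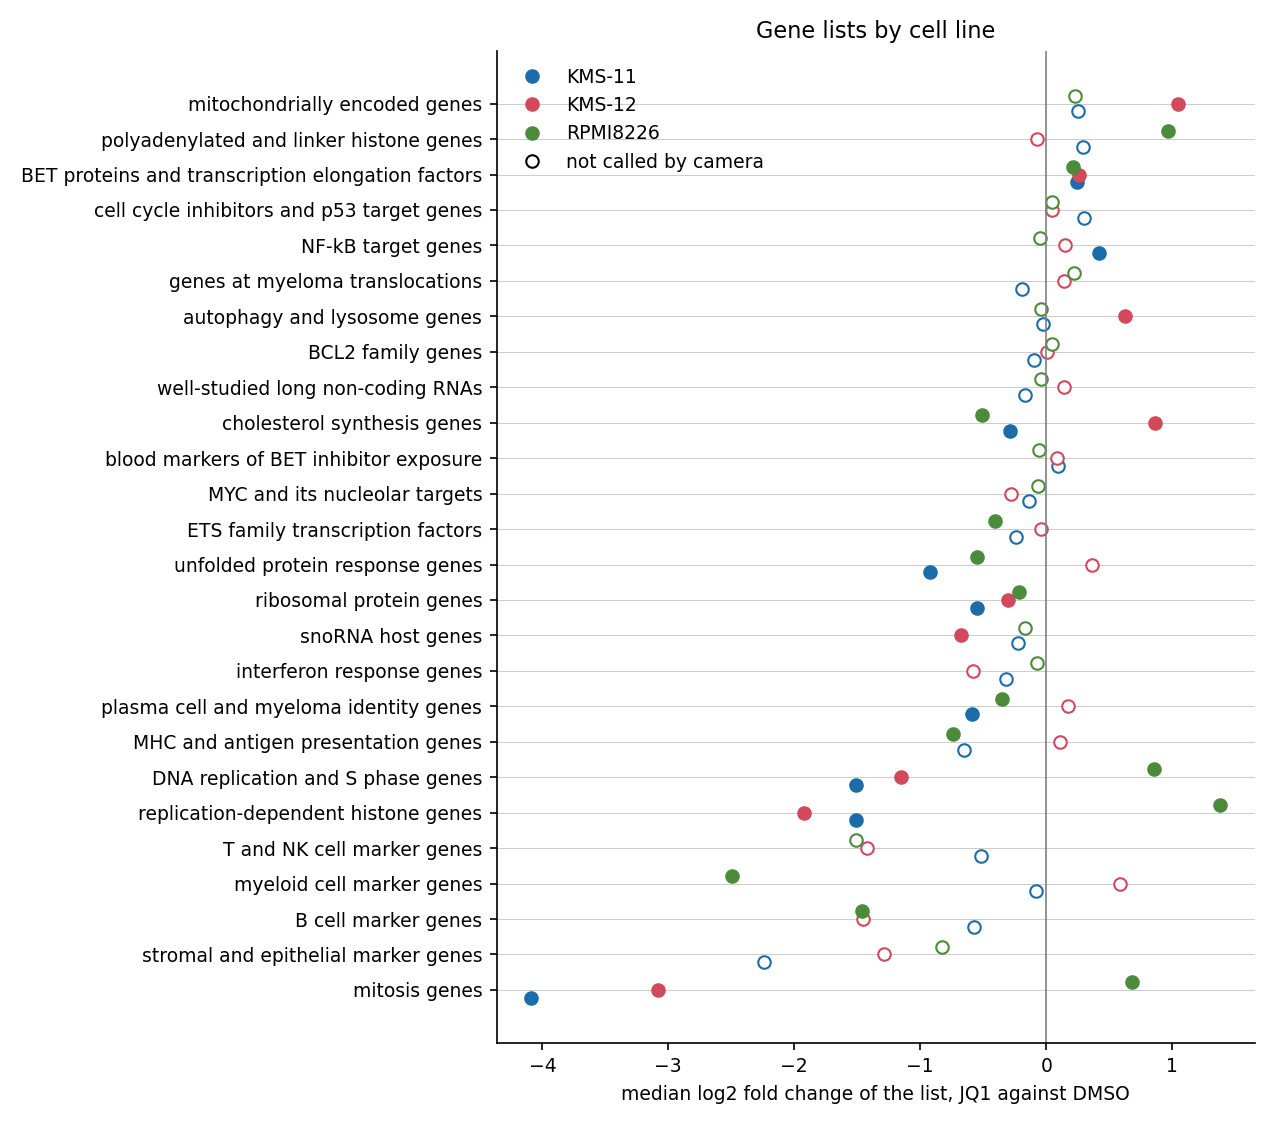
Median log2 fold change (JQ1 against DMSO) of the members of each of the 26 tested gene lists, by line; filled points were called by camera with the preset correlation. Mitosis genes stood at -4.09 in KMS-11, -3.09 in KMS-12 and 0.68 in RPMI8226; with library size alone the KMS-12 medians of the BET, plasma cell, blood marker, p53, BCL2, MHC, NF-kB, unfolded protein response, autophagy, long non-coding RNA and translocation lists turned negative, as did the KMS-11 medians of the BET, blood marker and mitochondrial lists.

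In KMS-11, taken alone, most genes of mitosis, DNA replication, ribosomal proteins and the unfolded protein response were lower. Of the mitosis genes 39 fell (median -4.09), and of the DNA replication genes 38 fell and 1 rose (41 and 1 adjusted over the list alone; median -1.51). Of the ribosomal protein genes 57 fell (60 adjusted over the list alone; median -0.55), and of the unfolded protein response genes 25 fell and 0 rose (median -0.92). VGLL3, a cofactor of TEAD factors, went from 0 to 92 reads, at least 38.7-fold higher. The transporter SLCO2B1 rose by 4.64 (SE 0.37) and the synaptic adhesion gene CLSTN2 in KMS-11 by 4.48 (SE 0.37; 5.12 without DMSO replicate 2). RUFY4 went from 595 reads to 0 (at least 157-fold lower), MKX from 329 to 0 (at least 86.8-fold), and MAB21L4 and TRAT1 from 155 each to 0 (at least 40.9-fold), as did LINC01226. DESeq2 did not call MKX and MAB21L4 (Benjamini-Hochberg adjusted p = 0.153 and 0.214, in ranges from 6.52e-27 and 1.38e-14). NF-kB targets were called with 11 rises and 5 falls (11 and 6 adjusted over the list alone; median 0.42, mean -0.09), a call lost at adjusted p = 0.418 with an estimated correlation in camera (Benjamini-Hochberg). With library size alone they had 7 rises and 6 falls (median 0.16). BIRC3, an inhibitor of apoptosis, rose by 3.51 (SE 0.12). In all, 4064 genes were higher and 4976 lower by edgeR, 45.0% higher against 23.8% with library size alone. Camera called 9 lists, the strongest being mitosis at a Benjamini-Hochberg adjusted p of 1.67e-17; with an estimated correlation the smallest was adjusted p = 0.418 and no list was called.

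In KMS-12 falls of mitosis genes came with rises of lysosome, sterol and mitochondrial genes. Of the mitosis genes 38 fell (median -3.09), of the replication-dependent histone genes 30 fell and 1 rose (34 and 1 adjusted over the list alone; median -1.92), and of the snoRNA host genes 15 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.67). Cholesterol synthesis genes had 18 rises and 3 falls with a median of 0.86, which was 0.09 with library size alone (9 rises, 7 falls); IDI1 rose by 2.58 (SE 0.14). Autophagy and lysosome genes had 24 rises and 3 falls with a median of 0.63 that turned to -0.09 with library size alone, and the 13 mitochondrially encoded genes all rose (median 1.05), of which 4 rose with library size alone (median 0.28). Unfolded protein response genes had 14 rises and 4 falls (15 and 6 adjusted over the list alone; median 0.36), against 4 and 14 with library size alone (median -0.41), and camera did not call them (Benjamini-Hochberg adjusted p = 0.0636). The chemokine CCL4 went from 1 read to 122. PLAAT4 rose by 6.04 (SE 0.24), SRPK3 by 5.96 (SE 0.29) and P2RY6, a receptor for UDP, by 5.76 (SE 0.32; 6.73 without DMSO replicate 2). The ETS gene ETV4 went from 1400 reads to 0, at least 326-fold lower, TSKU from 467 to 0 (at least 109-fold) and TMTC1 from 372 to 0 (at least 86.7-fold). PLOD2, a collagen lysyl hydroxylase, went from 214 to 0 (at least 49.9-fold) and the histone pseudogene H2BC27P from 203 to 0 (at least 47.3-fold). CDKN1A, the cell cycle inhibitor p21, rose from 11.6 ± 0.816 to 258 ± 2.66 CPM (SD, n = 2). In all, 4757 genes were higher and 6047 lower by edgeR, 44.0% higher against 7.49% with library size alone. Camera called 9 lists, among them cholesterol synthesis at a Benjamini-Hochberg adjusted p of 7.79e-06; with an estimated correlation the smallest was adjusted p = 0.578.

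In RPMI8226 genes of DNA replication and histones rose, and genes of antigen presentation, plasma cells, the unfolded protein response and cholesterol synthesis fell. Of the DNA replication genes 34 rose and 0 fell (38 and 0 adjusted over the list alone; median 0.85), of the replication-dependent histone genes 20 rose (28 adjusted over the list alone; median 1.38, and 1.41 at the bounds), and of the polyadenylated histones 10 rose (12 adjusted over the list alone; median 0.96). Of the 40 mitosis genes 3 passed, each higher (0 adjusted over the list alone and 0 with RLE scaling), and camera called the list (median 0.68). That call was lost at adjusted p = 0.790 with an estimated correlation in camera (Benjamini-Hochberg), and fry gave a Benjamini-Hochberg adjusted p of 0.308. Of 22 MHC and antigen presentation genes 16 fell and 0 rose (median -0.74), and of 26 plasma cell genes 15 fell (16 adjusted over the list alone; median -0.35). Of 31 unfolded protein response genes 13 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.55), as did 13 of 24 cholesterol synthesis genes (15 and 0 adjusted over the list alone; median -0.51) and 22 of 69 ribosomal protein genes (19 and 0 adjusted over the list alone; median -0.22). Camera called these 3 lists at Benjamini-Hochberg adjusted p-values of 7.99e-05, 0.000102 and 0.00189, and each call was lost at adjusted p = 0.339, 0.476 and 0.814 with an estimated correlation. The interferon, NF-kB and T and NK cell lists were not called by camera in this line, at Benjamini-Hochberg adjusted p-values of 0.114, 0.572 and 0.0609. Of 6 myeloid markers 5 fell (6 adjusted over the list alone; median -2.49) and of 13 B cell markers 6 fell (8 adjusted over the list alone; median -1.47, and -1.59 at the bounds). Immunoglobulin IGHA2 went from 195 reads to 0 (at least 55.8-fold lower), IGHG4 from 171 to 0 (at least 49.0-fold), and KLHL30 from 146 to 0 (at least 41.8-fold). The chemokine CCL1 went from 139 to 0 (at least 39.8-fold) and PTPRC, which encodes CD45, from 129 to 0 (at least 36.9-fold). MAP1A rose by 3.49 (SE 0.25), FAM222A by 3.47 (SE 0.37; 2.83 without JQ1 replicate 1) and PEG10, a gene derived from a retrotransposon, by 3.51 (SE 0.23). KRT15 in RPMI8226 passed at 4.06 (SE 1.04), lost without any single KMS-11 library (4.06 to 4.07) or either RPMI8226 DMSO replicate (4.74 and 3.57), and with no filter beyond 1 read (4.07). Its size rested on JQ1 replicate 1, with 1342 reads against 201 in replicate 2, and was 2.40 without that library and 4.81 without JQ1 replicate 2. In all, 3195 genes were higher and 4379 lower by edgeR. Camera called 13 lists, DNA replication at a Benjamini-Hochberg adjusted p of 4.96e-12 and MHC at 2.17e-06; with an estimated correlation the smallest was adjusted p = 0.193, for myeloid markers.

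**Figure D3:**
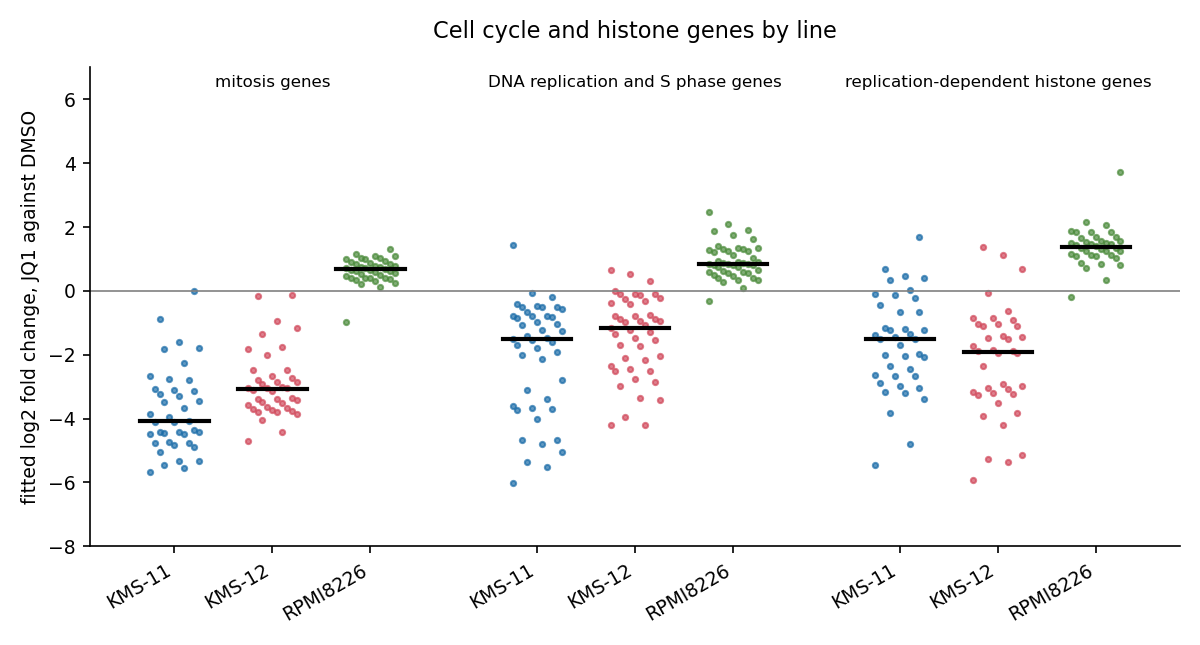
Fitted log2 fold change (JQ1 against DMSO) of each mitosis, DNA replication and replication-dependent histone gene, by line; points are genes, black lines are medians, and genes without reads in a group of that line are left out. The medians were -4.09, -3.09 and 0.68 for mitosis, -1.51, -1.15 and 0.85 for DNA replication, and -1.51, -1.92 and 1.38 for histones, with the same signs under each scaling.

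The response to JQ1 differed between lines for 7070 of 23493 genes (30.1%) in edgeR's test of any difference, and 1185 of those were called in opposite directions in 2 lines. The death receptor FAS rose by 1.12 in KMS-11 (SE 0.10), fell by 4.69 in KMS-12 (SE 0.16) and stood at 0.30 in RPMI8226 (SE 0.11), with an edgeR Benjamini-Hochberg adjusted p of 7.86e-12 for the difference. ZFP36, which destabilises AU-rich messages, rose from 14.5 ± 1.81 to 448 ± 18.9 CPM in KMS-12 and fell from 74.7 ± 6.76 to 42.1 ± 4.86 in RPMI8226 (SD, n = 2). SAT1, a polyamine acetyltransferase, rose by 0.94 and 1.57 in KMS-11 and KMS-12 and fell by 2.55 in RPMI8226. DUSP5, a phosphatase of ERK, and AHNAK rose in KMS-12 by 4.37 and 3.68, with values within 0.17 of no change elsewhere. CCDC141 fell by 4.83 in KMS-12 and by 1.18 in RPMI8226; RUBCN, a brake on autophagy, rose by 2.21 in KMS-12 and fell by 0.57 in RPMI8226. P4HB, a protein disulfide isomerase, and RHBDF2 fell in KMS-11 by 1.24 and 1.37 and rose in KMS-12 by 2.22 and 1.66. BIRC3 at 3.51 in KMS-11 stood at -0.31 and -0.16 in the other lines. These 10 genes had the smallest p, with an edgeR Benjamini-Hochberg adjusted p of 6.61e-10 or less.

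**Figure D4:**
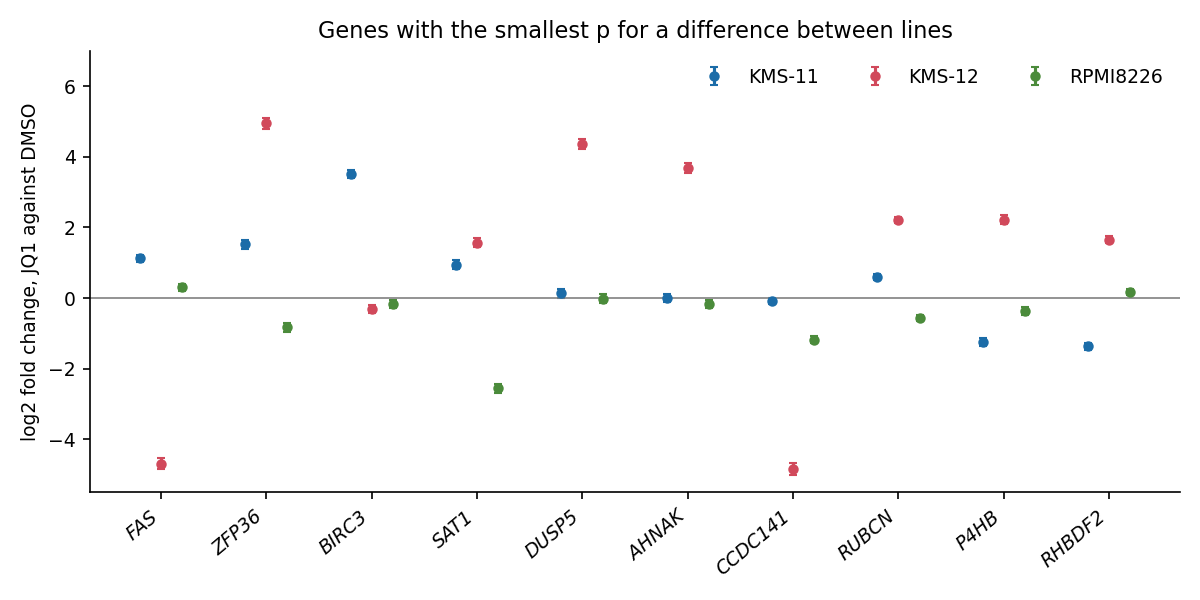
Log2 fold change (JQ1 against DMSO, with SE) in each line of the 10 genes with the smallest p for a difference between lines. FAS fell by 4.69 in KMS-12 alone, ZFP36 and DUSP5 rose most in KMS-12, BIRC3 rose in KMS-11, and SAT1 fell by 2.55 in RPMI8226.

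Some of the genes always taken, or taken from a list, also differed. CDKN1A rose by 4.48 in KMS-12 (SE 0.22), stood at 0.08 in RPMI8226 (SE 0.19) and fell by 0.61 in KMS-11 (SE 0.20), a fall lost without KMS-11 DMSO replicate 2 (-0.24; edgeR, Benjamini-Hochberg adjusted p = 0.277) or JQ1 replicate 2 (-0.46; 0.189), in a range from 9.93e-07 to 0.564 over the alternatives. The RPMI8226 value of CDKN1A was -0.09 without DMSO replicate 2 and -0.00 without JQ1 replicate 1. MCL1, a survival gene of plasma cells, rose by 1.37 in KMS-11 and 2.80 in KMS-12 and stood at -0.46 in RPMI8226, a fall lost without JQ1 replicate 2 (-0.34). IRF4, on which myeloma cells depend, stood at 0.75 in KMS-12 (-0.02 with library size alone), -0.72 in RPMI8226 and -0.20 in KMS-11. The KMS-11 value of IRF4 was -0.37 without JQ1 replicate 2 and -0.055 without JQ1 replicate 1, the smallest fall over the alternatives. PRDM1 rose by 1.09 in KMS-11 and 2.14 in KMS-12, against 0.32 in RPMI8226, which did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.0863, in a range from 0.00612 to 1 over the alternatives). It passed without either KMS-11 JQ1 replicate and with no filter beyond 1 read, at 0.32 in each case. CDC45 fell by 5.52 in KMS-11 and 4.21 in KMS-12 and rose by 0.95 in RPMI8226. BRD2 rose by 0.60, 1.30 and 0.43, the RPMI8226 call lost without its JQ1 replicate 1 (0.28). Pairwise, edgeR called 4699 genes between KMS-12 and KMS-11, 2685 between RPMI8226 and KMS-11 and 5505 between RPMI8226 and KMS-12, and camera called 11, 9 and 12 lists. None of these held with an estimated correlation, the smallest being adjusted p = 0.0541 with an estimated correlation in camera (Benjamini-Hochberg), where 2, 4 and 2 lists had an unadjusted p under 0.05, while fry called 8, 7 and 19. Across genes, which are not independent replicates, the fold changes of KMS-11 correlated with those of KMS-12 at a Pearson r of 0.376 and with those of RPMI8226 at 0.374, and KMS-12 with RPMI8226 at 0.306.

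Among long non-coding RNA genes, 641 of 5197 tested rose and 1250 fell in the average of the lines by edgeR. Falls made up 24.1%, against 29.8% in matched protein-coding sets, and rises 12.3% against 8.76%, with 0 of 10000 matched sets as extreme in either case. Rises went the other way in KMS-11, at 7.91% against 10.8%, and were 11.1% against 7.15% in KMS-12 and 6.93% against 5.64% in RPMI8226. ADAMTSL4-AS2 rose by 2.36 (SE 0.16), ADAMTSL4-AS1 by 2.16 (SE 0.12), B4GAT1-DT by 2.11 (SE 0.13), MIR22HG by 2.06 (SE 0.20) and LINC00910 by 1.89 (SE 0.12). LINC01226 went from 155 reads to 0 in KMS-11, 231 to 1 in KMS-12 and 175 to 2 in RPMI8226. UICLM was at least 39.1-fold lower in KMS-12 and fell by 5.19 in RPMI8226 (SE 0.34). ITGB2-AS1 fell by 4.17 in KMS-11 (SE 0.68) and 4.61 in RPMI8226 (SE 0.32), PRR7-AS1 was at least 26.6-fold lower in KMS-12, and LHFPL3-AS1 had 316 DMSO and 41 JQ1 reads in KMS-11. Because strand use in counting is not given, reads of the antisense genes cannot be told from those of their partners.

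MALAT1 and NEAT1, long RNAs of the nucleus, took a growing share of all counts. MALAT1 went from 3.80 ± 0.262% to 15.5 ± 1.40% in KMS-11, 8.54 ± 0.669% to 25.8 ± 0.0879% in KMS-12 and 4.35 ± 0.335% to 6.44 ± 0.180% in RPMI8226 (SD, n = 2). NEAT1 went from 1.66 ± 0.274% to 3.27 ± 0.391%, 2.32 ± 0.248% to 9.63 ± 0.538% and 1.33 ± 0.194% to 1.97 ± 0.279%. In the average of the lines MALAT1 rose by 1.75 (SE 0.09), NEAT1 by 1.55 (SE 0.11) and LINC01004 by 0.93 (SE 0.09), and MIAT fell by 1.03 (SE 0.07), with an edgeR Benjamini-Hochberg adjusted p of 6.19e-08 or less for each. With this, genes detected fell from 28396 ± 639 to 26828 ± 419 in KMS-11, from 27444 ± 56.6 to 24467 ± 33.2 in KMS-12 and from 28806 ± 590 to 26497 ± 352 in RPMI8226, and the 10 most abundant genes went from 10.05% to 24.5%, 13.6% to 39.3% and 9.42% to 12.7% of counts.

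**Figure D5:**
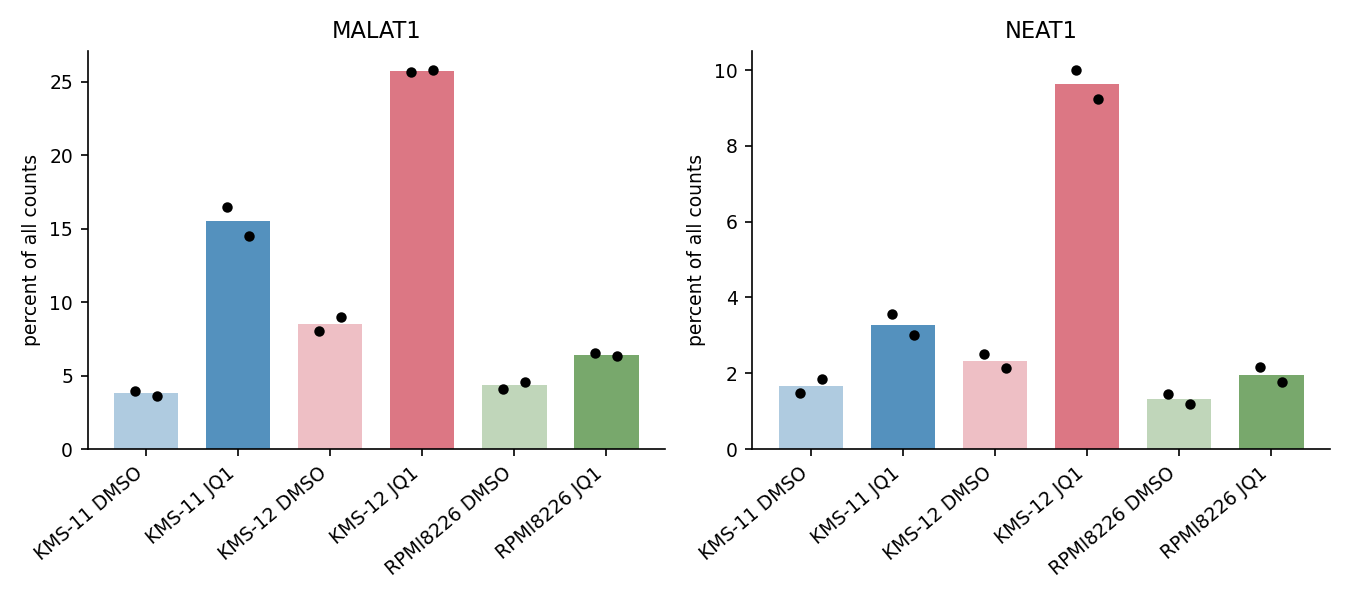
Percent of all counts taken by MALAT1 (left) and NEAT1 (right) in each library; bars are group means and points the 2 libraries of a group. MALAT1 reached a mean of 25.8% in the KMS-12 JQ1 libraries against 8.54% in DMSO, and 6.44% against 4.35% in RPMI8226.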

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

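The tests of a weaker response and of CDKN1A in the division genes, of nuclear RNA and of other messages for MALAT1, and of read supply and of a subline for the silenced genes were chosen only after the result was seen. The counts, lists and genes with a span given here were singled out because the lines differed in their response to JQ1, by a test of the difference itself, while the genes that lost expression were taken by their reads. Between all lines 7070 genes differed by edgeR, with 4699 for KMS-12 minus KMS-11, 2685 for RPMI8226 minus KMS-11 and 5505 for RPMI8226 minus KMS-12, and camera with its preset correlation called 11, 9 and 12 lists for these differences. With an estimated correlation camera called 0 lists for each of them, the smallest being adjusted p = 0.0541 with an estimated correlation (Benjamini-Hochberg), for the myeloid markers and NF-kB targets in RPMI8226 minus KMS-11. In the same order, 2, 4 and 2 lists had an unadjusted p under 0.05 with an estimated correlation in camera, and fry called 8, 7 and 19.

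Each list given here was called by camera with the preset correlation for the pair of lines named, and the Benjamini-Hochberg adjusted p of camera with an estimated correlation follows it. For RPMI8226 minus KMS-11 the median log2 difference of responses was 4.68 for mitosis, where 37 of 40 genes were higher, 2.47 for DNA replication (42 of 45) and 3.03 for replication-dependent histones (27 of 40; 39, 43 and 33 adjusted over the list alone), with adjusted p = 0.287, 0.273 and 0.287 with an estimated correlation in camera (Benjamini-Hochberg). For the same pair the ribosomal proteins had a median of 0.33, with 8 of 69 genes higher, at adjusted p = 0.592 with an estimated correlation in camera (Benjamini-Hochberg) and 0.187 in fry. NF-kB targets had -0.51, with 8 of 23 genes lower and 1 higher (11 and 3 adjusted over the list alone), and myeloid markers -2.44, with 2 of 6 lower, each at adjusted p = 0.0541 with an estimated correlation in camera (Benjamini-Hochberg). RPMI8226 minus KMS-12 gave -0.86 for autophagy, -1.37 for cholesterol synthesis, -0.85 for mitochondrial genes, -1.09 for MHC genes, 0.83 for polyadenylated histones and -1.13 for plasma cell genes. These had adjusted p = 0.255, 0.289, 0.323, 0.289, 0.323 and 0.323 with an estimated correlation in camera (Benjamini-Hochberg). KMS-12 minus KMS-11 gave 1.29 for the unfolded protein response, -0.56 for snoRNA hosts and 0.32 for well-studied long non-coding RNAs, at adjusted p = 0.451, 0.693 and 0.693 with an estimated correlation in camera (Benjamini-Hochberg).

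Mitosis and DNA replication genes fell in KMS-11 and KMS-12 and not in RPMI8226. Untreated or mislabelled RPMI8226 JQ1 libraries would leave other genes unmoved, but 4996 genes called in one direction in both KMS lines moved the same way in RPMI8226 by a median of 0.523 (bootstrap 0.506 to 0.539), and 87.1% had the same sign. The bootstrap resampled genes, which are not independent replicates, so its bounds do not measure the spread between libraries. A weaker response would give smaller falls, whereas the DNA replication genes in RPMI8226 had a median of 0.85 with quartiles of 0.59 and 1.27. Reads in RPMI8226 DMSO were low for some division genes and not for others. UBE2C had 70, against 1801 in KMS-11 and 1112 in KMS-12, and CDC45 had 165 against 468 and 430. ORC1 had 1029 against 1040 and 870. Among histone genes H3C2 had 775 against 4728 and 4269, and H2BC6 had 211 against 249 and 247. These sums hide a spread between KMS-11 DMSO replicates 1 and 2. Those libraries had 521 and 1280 reads of UBE2C, 186 and 282 of CDC45, and 376 and 664 of ORC1. Whether the state of the DMSO cultures set the opposite sign was not tested. Scaling left a gap of at least 3.71 between the mitosis medians. The largest move of a line's median of all genes was -0.76, in KMS-12 with library size alone, so these scalings could not have closed it. CDKN1A would have to rise in both KMS lines as the common route, and it stood at -0.61 in KMS-11. That value was -0.24 without DMSO replicate 2 and -0.46 without JQ1 replicate 2 of that line, where its call was lost. A line-specific arrest of the cell cycle remains a hypothesis found on these same data, and cell numbers were not used here.

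MALAT1 and NEAT1 took a larger share of the counts in JQ1 libraries. If nuclear RNA had been enriched in the extracts, other nuclear RNAs would rise too. The median of 7 such RNAs was -0.19 in KMS-11 and -0.37 in KMS-12, at least 2.48 below MALAT1 in both lines. That comparison takes the 7 RNAs as otherwise unmoved by JQ1, which was not tested, so a smaller enrichment is not excluded. If all other messenger RNA had fallen with MALAT1 unchanged, transcripts of the mitochondrial genome would seem to rise as far as MALAT1, and their median lay at least 1.31 below it in both lines. This takes mitochondrial transcripts as unchanged and bears only on a fall that would explain the whole rise. A smaller fall of other messages is not excluded, since in KMS-12 the mitochondrial median was 1.05 where MALAT1 rose by 2.36. MALAT1 rose by at least 1.59 in both KMS lines under each of the 4 scalings. With library size alone that rise restates the larger share of counts, which no scaling changes, so these values do not test the share. A higher level of these RNAs under JQ1 may be the biological reading, as a hypothesis on relative amounts, and amounts per cell were not analysed here.

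Expression was lost in 27 genes that had at least 100 DMSO reads in a line and 0 JQ1 reads, 6 in KMS-11, 12 in KMS-12 and 9 in RPMI8226, with falls of at least 26.6-fold to at least 326-fold. At an unchanged level each would have had at least 79.7 JQ1 reads, so fewer reads left for other genes would not alone give 0. The choice of genes with at least 100 DMSO reads fixed this outcome in advance, so it is no independent test. Loss of the chromosome segment would take neighbours along, yet the 163 expressed neighbours within 250 kb of 22 of these genes had a median of -0.18 (bootstrap -0.38 to -0.09). These bounds too come from resampling genes and do not measure the spread between libraries. Other lost genes were not counted as neighbours, and IGHA1, IGHA2 and IGHG4 on chromosome 14 were all lost in RPMI8226. The lower quartile of the neighbours was -1.38. A median pooled over loci argues against segment loss as the common cause, but cannot exclude it at a single locus. JQ1 libraries made from another subline would also show genes gained from nothing, but 0 genes had at least 100 JQ1 reads and none in DMSO, and 1, VGLL3 in KMS-11 with 92 JQ1 reads, was higher by at least the lowest of these bounds (at least 38.7-fold). Loss of BET-dependent transcription is a hypothesis that these tests leave open.

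Among genes named in the results, the span between the lines with the highest and lowest log2 change is given in parentheses, for genes whose difference passed edgeR's test. Spans were largest for PLAAT4 (7.995), H3C2 (7.29), CDC45 (6.47), FAS (5.81), ZFP36 (5.77), H2BC13 (5.69), SLCO2B1 (5.67), CENPA (5.29) and CDKN1A (5.08). Below these came CCDC141 (4.75), LYZ (4.63), SRPK3 (4.63), UBE2C (4.58), CDC6 (4.39), DUSP5 (4.38), SAT1 (4.12) and MIR22HG (4.09). The next genes were AHNAK (3.86), BIRC3 (3.82), PRC1 (3.79), ORC1 (3.73), ITGAM (3.72), MAD2L1 (3.55), MYEOV (3.47), P4HB (3.46) and CD8A (3.42). They were followed by H2BC12 (3.26), MCL1 (3.26), CD68 (3.15), RHBDF2 (3.02), CLU (2.99), MZB1 (2.95), IDI1 (2.91), LINC00910 (2.89) and EPPK1 (2.87). Lower spans belonged to RUBCN (2.78), CD28 (2.74), ELF4 (2.67), ISG20 (2.61), CTSS (2.61), SNORD3B-2 (2.49), STARD4 (2.46), TP53INP1 (2.45), MAP1A (2.38), NQO1 (2.34), ADAMTSL4-AS1 (2.33), IQCN (2.33) and ADAMTSL4-AS2 (2.31). Then came NEAT1 (2.22), PEG10 (2.19), GADD45B (2.06), HLA-DMA (2.01), TNFRSF10B (1.90), HLA-DRA (1.87), EPCAM (1.87), PLEK (1.83), NEU1 (1.83) and PRDM1 (1.82). Further down stood MALAT1 (1.77), MCM6 (1.75), FAM222A (1.69), WIPI1 (1.62), SNHG12 (1.60), MIAT (1.56), SLC19A1 (1.52), IRF4 (1.47), STAT2 (1.44), TM7SF2 (1.43) and BCL2L11 (1.43). Smaller differences were those of BMF (1.37), LINC01004 (1.29), HLA-DQA1 (1.29), BRD3 (1.20), ITGA4 (1.19), PSMB8 (1.17), MT-ATP8 (1.16), HSPD1 (1.15), NFKBIA (1.14), ODC1 (1.04) and MT-CYB (1.02). The smallest were those of ERF (0.98), RPS19 (0.92), BRD2 (0.86), FDPS (0.83), SNHG16 (0.83), HEXIM1 (0.72), ATP6V0D1 (0.66), RPL13A (0.63), H3-3A (0.61), BOP1 (0.56) and GABPA (0.53). For genes without reads in a group the span rests on fitted values and is not a fold: PTPRC (12.34), TMTC1 (12.31), ETV4 (10.74), CCL4 (9.77), TSKU (9.44), H2BC27P (9.40), P2RY6 (9.33), PLOD2 (7.73), PRR7-AS1 (7.52), IGHA2 (7.38), RUFY4 (7.28), NCAM1 (3.72), ADGRG1 (3.59) and KRT18 (3.05).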

How the results depend on the processing

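No test in this part was chosen after the result was seen. Of 4566 values of named genes under the alternatives, 4443 kept direction and side of the threshold, 91 lost the call, 21 gained it and 11 changed sign. For JQ1 against DMSO, average of the 3 lines, edgeR called 7141 genes with a mean of at least 10 CPM, which tests fewer genes, and 4155 against a 1.5-fold change, a stricter question. The same settings gave 5918 and 3940 for JQ1 against DMSO in KMS-11, 6594 and 5612 for JQ1 against DMSO in KMS-12, 4823 and 2598 for JQ1 against DMSO in RPMI8226, and 345 and 850 for long non-coding RNA genes. The genes called in the same direction in all 3 lines numbered 678 against 1.5-fold and 1806 at an adjusted p under 0.01, and FLI1 stayed at -0.32 without passing 1.5-fold. With library size alone 11281 genes differed between the lines, and of the calls 307 of the average and 974 of KMS-12 turned to the opposite direction. By its construction that setting moves all genes of a line by about the same amount, with medians moved by -0.33 in the average, -0.25 in KMS-11, -0.76 in KMS-12 and -0.03 in RPMI8226. It turned the sign of SERPINI1 (-0.058 in the average, -0.13 in KMS-11 and -0.46 in KMS-12), IRF4 in KMS-12 (-0.018) and CD68 in the average (-0.050). With an estimated correlation camera called 0 of the 26 lists in the average, 0 at an unadjusted p under 0.05, and fry called 23.

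Leaving out each library in turn, with the lone library of a group assumed to vary like the others, gave 10642 to 11669 genes in the average, 7090 to 9132 in KMS-11, 8338 to 11484 in KMS-12 and 5165 to 8571 in RPMI8226. It gave 5473 to 8017 genes for the difference between lines, 2172 to 3177 in the same direction, 1671 to 1897 long non-coding RNA genes, 8 to 12 lists and -0.38 to -0.25 for FLI1. Signs turned for FLI1 in KMS-12 (0.057 without KMS-12 DMSO replicate 1, lowest -0.13), SERPINI1 in KMS-11 (-0.078 without KMS-11 DMSO replicate 1, highest 0.37) and CDKN1A in RPMI8226 (-0.094 without RPMI8226 DMSO replicate 2, -0.0047 without RPMI8226 JQ1 replicate 1, highest 0.28). The same held for LYZ, average of the 3 lines (-0.69 without RPMI8226 JQ1 replicate 2, highest 1.13) and ITGA2B, average of the 3 lines (0.040 without KMS-12 JQ1 replicate 2, lowest -0.57). Fits on the 4 libraries of a line alone kept 6902 of the 8694 calls also tested there in KMS-11, 10411 of 10445 in KMS-12 and 7051 of 7268 in RPMI8226.

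Replicate numbers did not clearly pair the libraries. Same-numbered libraries of a line deviated together at a correlation of 0.106 in KMS-11, 0.0122 in KMS-12 and 0.104 in RPMI8226. Between lines the correlations ran from -0.0374 to 0.0472, so weak pairing in KMS-11 and RPMI8226 is not excluded. With a replicate block edgeR called 11845 genes for JQ1 against DMSO, average of the 3 lines, and 11337 of the 11509 calls were kept. The block gave 9637 for JQ1 against DMSO in KMS-11, 11244 for JQ1 against DMSO in KMS-12 and 8421 for JQ1 against DMSO in RPMI8226. It gave 8048 where the JQ1 response differs between the 3 lines, 3322 genes called in the same direction in all 3 lines, 1923 for long non-coding RNA genes, JQ1 against DMSO, average of the 3 lines, 10 lists and -0.32 for FLI1. Under it CDKN1A in KMS-11 lost its call, and FLI1 and MYC in KMS-11 and PRDM1 in RPMI8226 gained one. Depth limits what can be said of SMILO in KMS-12 and of genes under the floor of 3 counts.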

Other observations

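Every test in this part was fixed before its own result was seen, but the NRF2 list was drawn up, without NQO1, after the rise of NQO1 had been seen, and the comparison of line-enriched genes after the silenced genes had been. Among genes of the oxidative stress response HMOX1, which degrades heme, rose by 2.07 on the log2 scale in the average of the lines (edgeR), SRXN1 by 1.96, PRDX1 by 1.54, TXNRD1 by 1.17 and GCLC, the rate-limiting enzyme of glutathione synthesis, by 1.11. CBR3, BLVRB and ABCC2 fell by 1.41, 0.90 and 0.67, and the cystine transporter SLC7A11 stood at -0.94 without passing. Of 24 measured NRF2 targets 15 rose and 6 fell by edgeR. Their median was 0.60 in the average (0.25 with library size alone), 0.73 in KMS-11, 0.67 in KMS-12 (-0.10 with library size alone) and 0.19 in RPMI8226. Camera gave an unadjusted p of 8.34e-05 for this single list, and p = 0.0661 with an estimated correlation. An NRF2 target response to JQ1 is a hypothesis, which the list met by camera with the preset correlation, and which is weaker with library size alone.

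Genes that set a line apart had lower medians under JQ1 than matched genes. They were taken as at least 4-fold higher in the line's DMSO replicate 1 than in replicate 1 of both other lines, and their change was measured against DMSO replicate 2. The median was -0.41 for 958 genes in KMS-11 (matched sets -0.02), -0.91 for 1126 in KMS-12 (-0.13) and -1.03 for 1193 in RPMI8226 (-0.05), with 0 of 10000 sets matched on expression as low in any line. The smallest gap to the lower bound of matched sets was -0.33, which may reflect a dependence of line-specific transcription on BET proteins, as a hypothesis.

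Genes at myeloma translocations served as a check of the line labels and are given as levels. In DMSO, KMS-11 had NSD2 at 2546 ± 382 CPM, FGFR3 at 2597 ± 26.6, MAF at 1641 ± 35.9 and CCND2 at 1672 ± 2.21, KMS-12 had CCND1 at 584 ± 50.4, and RPMI8226 had MAF at 1070 ± 150 and CCND2 at 1074 ± 45.2 (SD, n = 2). With JQ1, FGFR3 in KMS-11 stood at 928 ± 52.5, NSD2 in KMS-11 at 5075 ± 1557 and MYEOV in KMS-12 at 715 ± 25.4, against 269 ± 9.29 in DMSO.

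Labellings of the libraries within lines were drawn, 100 of 108, with the real one among them. Of these, 1 gave as many genes in the average, the real one with 11509; the highest other gave 6984 and came from labellings that swap both treatments of whole lines. For long non-coding RNA genes 1 labelling gave as many, the real one with 1891 against 933. Both counts were thus largest under the real labels. Labellings that mix treatments within a line add the JQ1 effect to the spread. The comparison therefore cannot exclude other differences between the JQ1 and DMSO cultures. For FLI1 6 labellings gave a change as large as 0.32, the highest other 0.36, and for the 10 lists 33 did, the highest other 16, so that chance is not excluded for these.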
